A study of Fragilariopsis cylindrus with 66 samples.

How the data were processed

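RNA from cultures of the diatom Fragilariopsis cylindrus CCMP3323 was isolated with a column kit and made into libraries with a stranded kit that selects poly(A) RNA, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.38, STAR 2.7.9a and HTSeq 0.13.5, without their order or settings. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The authors deposited 2 tables of raw counts, whole numbers of reads per gene ID with 1 column per library, and nothing in them was normalized or pooled. The 66 columns were matched to the 66 libraries by name. Reads shared between near-identical copies or alleles of a gene, and reads of overlapping or antisense genes, could not be told apart from the counts.

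Groups were taken from the labels: light, time in darkness or time after light return, within each experiment, with 3 libraries per group and 22 groups in all. In the 3-month table the 10 most abundant IDs held 2.79% to 47.6% of a library's counts, and the share ran from 22.8% to 65.97% in the 1-month table. A total of 23 IDs had no count in the 3-month table and 261 in the 1-month table. Replicates of a group differed by more than sampling noise in every pair, with chi-square per degree of freedom of at least 10.2 in the 3-month and 4.60 in the 1-month table.

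Each experiment was fitted by itself with edgeR 4.0.16 in R 4.3.3. IDs were filtered with filterByExpr by group, which left 22642 IDs in the 3-month and 5056 in the 1-month table. Libraries were scaled by TMM, with factors from 0.33 to 1.75 and from 0.31 to 1.99. All groups of an experiment shared 1 robust quasi-likelihood fit of group means, and contrasts were tested with glmQLFTest. Calls are IDs with a Benjamini-Hochberg adjusted p under 0.05, and standard errors are the log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.32 in the 3-month and 0.52 in the 1-month experiment. Of the comparisons, 29 within an experiment and 2 interactions between experiments were fixed before the data were examined, and 2 were added afterwards. Interactions were tested in a joint fit of both tables. Intervals for low counts are exact binomial intervals at the 95% level and, like the floor of 3 counts per library, cover counting error only.

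Trajectory groups were formed by k-means (k = 8) on standardized mean log2 CPM with a prior count of 2. The test was checked on simulated data with the means, dispersions and library sizes of the real libraries and 200.0 changed IDs. For 6 h of darkness against light, simulated over 22642 IDs, 29% of 2-fold and 71% of 4-fold changes were recovered, with 1 false call. The shares were 16% and 69% with 3 false calls for 2 months of darkness against light, 15% and 70% with 7 for 24 h against 30 min after light return, and 13% and 71% with 6 for day 7 against light. For 1 month of darkness against light in the 1-month experiment, simulated over 5056 IDs, the shares were 0% and 7%, with 2 false calls. For 30 min after light return against 1 month of darkness they were 0% and 7%, with 0 false calls. The adjusted p is stricter where few IDs change, so these shares hold for 200 changed IDs.

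The 31 gene lists, fixed at the same time as the comparisons, name gene products, and nothing used here pairs the IDs with names, so no list was tested. The tests of those lists and their alternatives were not run for the same reason. IDs were named instead by a rule fixed beforehand: in each of 6 main comparisons, the 2 IDs that rose most and the 2 that fell most among called IDs with a mean of at least 10 CPM over the 6 libraries and libraries that did not overlap between the groups. The alternatives were RLE scaling factors, library totals alone, no low-count filter, only the compared groups in the fit, the replicate number as a block, DESeq2 1.42.0, and each library left out in turn. Leaving out the 7 IDs that dominated 30 min after light return was added after the data were seen.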

Results

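Transcript abundance was measured by RNA sequencing in Fragilariopsis cylindrus CCMP3323, a diatom of polar seas, grown at 0 °C under a light setting of 30 µmol quanta per m² per second. The cultures were sampled in full light, during prolonged darkness and after light was returned, in 2 experiments named after the length of the dark period. The 3-month experiment held 48 libraries in 16 groups, with totals of 6806394 to 18633143 counts per library. The 1-month experiment held 18 libraries in 6 groups, with totals of 287268 to 3042427 counts. Every group had 3 libraries, which the labels call biological replicates from triplicate culture systems. Samples taken at 3 months of darkness were not analysed here, so comparisons with 2 months of darkness also hold whatever the third month changed. Each table listed the same 24401 gene IDs. The IDs are plain numbers that the files do not pair with gene names, so transcripts are described by ID and by the course of their abundance. The counts are shares of a library, and RNA per cell was not measured.

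The transcriptome of the 3-month experiment moved away from the light state throughout darkness and moved back within days of light return. The root mean square log2 difference between a library and the light libraries was 0.76 ± 0.07 (SD, n = 3) among the light libraries themselves. It was 1.61 ± 0.07 after 6 h of darkness, 2.55 ± 0.15 after 6 days and 2.87 ± 0.08 after 2 months. It reached 3.17 ± 0.20 at 30 min after light return and then dropped to 2.37 ± 0.09 at 24 h and 1.31 ± 0.09 at 3 days. At 7 days it was 1.59 ± 0.14. The number of IDs called against light at an adjusted p under 0.05 in edgeR's quasi-likelihood test was 9480.0 after 6 h, 13237 after 3 days, 13976 after 6 days, 15769 after 1 month and 15927 after 2 months of darkness, as the plot of called IDs by time shows. It was 16045 at 30 min, 15377 at 2 h and 16064 at 6 h after light return, and 6229 on day 3. Its order within darkness depended on the fit, since the 2 groups fitted by themselves gave 15225 at 1 month and 14651 at 2 months, and library totals alone 14326 at 3 days and 13145 at 6 days. How these calls split between higher and lower depended on the scaling of the libraries and, in some comparisons, on the low-count filter, the groups in the fit, the replicate block, single libraries or the 7 IDs that dominated 30 min after light return. Splits that turned, or moved by more than 10 percentage points with the scaling, are given beside the main ones.

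**Figure D1:**
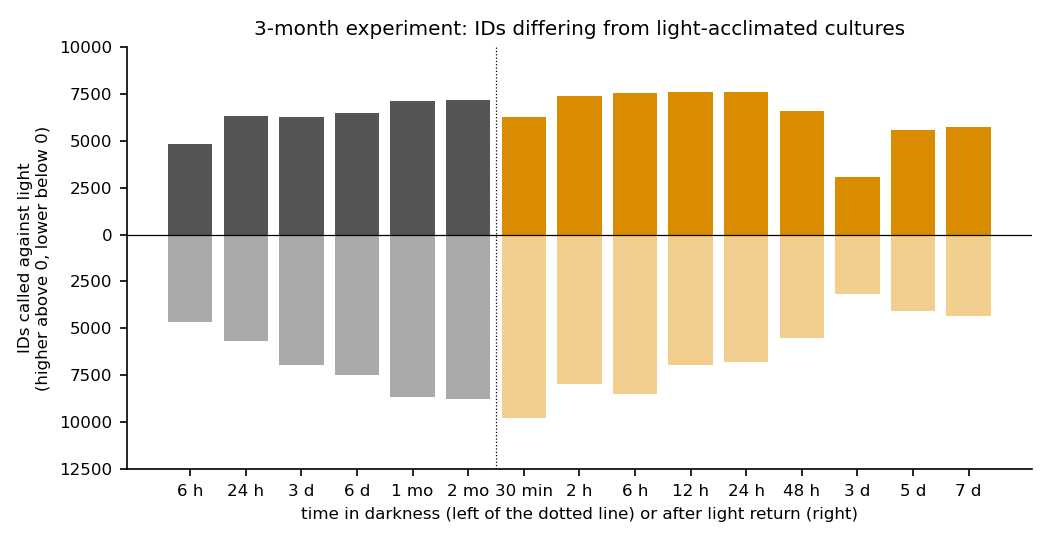
IDs of the 3-month experiment called against light at each time (edgeR, adjusted p under 0.05, 3 libraries per group). Bars above 0 count higher IDs and bars below 0 lower IDs, with dark bars for darkness and orange bars for light return. The count was 9480 after 6 h of darkness, 15927 after 2 months, 16045 at 30 min after light return and 6229 at 3 days.

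The entry into darkness was read from 6 h of darkness against light. Of 22642 IDs tested, 4828 were higher and 4652 lower after 6 h. Levels are given as CPM, the usual count scaled by effective library size. ID 268086 rose from 5.25 ± 1.96 CPM (SD, n = 3) in light to 1527 ± 687, a log2 fold change of 8.19 ± 0.56 (SE, adjusted p = 8.26e-14). ID 217774 rose from 1.76 ± 0.23 to 256 ± 24.3 CPM, by 7.17 ± 0.94 on the log2 scale (adjusted p = 9.59e-08). ID 158325 went from 60.4 ± 8.75 CPM down to 0.24 ± 0.20 and fell by 7.88 ± 0.55 on the log2 scale (adjusted p = 1.07e-13). ID 268220 went from 34.3 ± 5.85 CPM down to 0.16 ± 0.18 and fell by 7.63 ± 0.77 (adjusted p = 4.01e-10). Without replicate 2 of 6 h, IDs 158325 and 268220 kept 2 counts and 1 count after 6 h, with ratios of light to 6 h of 476 (131 to 3929.8) and 546 (97.7 to 21576). With RLE scaling factors the split was 3744 higher and 5825 lower, and with DESeq2 it was 4062 and 6315. Without the 7 dominant IDs it was 4290.0 and 5065, and the 2 groups fitted by themselves gave 4201 and 4722. Leaving out replicates 1, 2 and 3 of light gave 3917 and 4016, 4272 and 4316, and 4137 and 4182.

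More IDs differed from light on the following days of darkness, and whether those called at 6 h moved further was not tested. After 24 h, 6316 IDs were higher and 5653 lower than in light, and after 3 days 6259 were higher and 6978 lower. After 6 days 6507 were higher and 7469 lower. At 24 h the excess of higher IDs turned to 5000.0 and 6538 with RLE scaling factors, 5327 and 6870.0 with DESeq2, 5352 and 6198 without the 7 dominant IDs, and 4280.0 and 4745 in a fit of the 2 groups alone. With library totals alone, the split was 3832 higher and 6441 lower at 24 h, 2744 and 11582 at 3 days, and 3076 and 10069 at 6 days.

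Long darkness was read from 1 and 2 months against light. After 1 month 7115 IDs were higher and 8654 lower, and after 2 months 7158 were higher and 8769 lower. ID 251186 had no count in the 3 light libraries and 267 ± 34.1 CPM (n = 3) after 2 months. It was at least 772-fold higher, taking 3 counts per library as the floor. ID 237035 had 1 count in light and 226 ± 108 CPM after 2 months, a ratio of 6020.3 with a 95% counting interval of 1080.1 to 237831. ID 188077 had 699 ± 527 CPM in light and no count after 2 months, at least 1916-fold lower. ID 258839 had 388 ± 399.5 CPM in light and no count after 2 months, at least 1062-fold lower. Adjusted p was 2.17e-16, 8.58e-15, 6.81e-13 and 1.77e-11 for these 4 IDs in that order. Without replicate 1 of light the bounds were 1083-fold for ID 188077 and 431-fold for ID 258839, and ID 237035, then without a count in light, was at least 730.3-fold higher. Without replicate 2 of light its ratio was 3619.5 (649 to 142988). With RLE scaling factors the split was 5327 higher and 10374 lower at 1 month, and 5249 and 10555 at 2 months. DESeq2 gave 5557 and 10700 at 1 month, and 5465 and 10848 at 2 months.

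The second month of darkness was read from 2 months against 1 month, a comparison added after the data were seen. It gave 893 IDs that were higher at 2 months and 1418 that were lower. The 2 groups fitted by themselves gave 4242 called IDs. Leaving out replicate 2 of 1 month gave 1370.0 called IDs, leaving out replicate 1 of 2 months 1245, and leaving out replicate 3 of 2 months 1225. Scaling by library totals alone, 807 IDs were higher and 839 lower.

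Across the 16 groups of the 3-month experiment, 22489 of the 22642 IDs tested (99.3%) changed in edgeR's quasi-likelihood test of any difference. Their profiles were sorted into 8 trajectory groups by k-means clustering. When the groups were formed from replicates 1 and 2, 80.04% of IDs were placed in the same group by replicate 3, against 13.1% by chance. The IDs and the scaling came from all replicates, and no other number of groups was tried. The share thus shows similar time courses in the replicates and does not decide the number of groups. Group 1, with 3879 IDs, fell within hours of darkness: its median log2 difference from light was -1.28 ± 0.05 (SD, n = 3) at 6 h and -2.82 ± 0.30 at 6 days. It lay at -2.36 ± 0.34 at 30 min after light return, at -0.12 ± 0.13 at 6 h and at 0.92 ± 0.05 at 24 h. Group 2, with 3057 IDs, stood at -0.10 ± 0.10 after 6 h of darkness and at -3.14 ± 0.15 after 2 months. It still stood at -3.31 ± 0.12 at 6 h after light return, and was back at -0.02 ± 0.14 on day 3. With library totals alone, group 1 stood at 0.37 at 6 h after light return and group 2 at 0.45 on day 3.

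The other trajectory groups rose in darkness, answered light return or, in group 3, lay below light in long darkness and after light return. Group 8, with 2159 IDs, stood at 2.22 ± 0.13 after 1 month of darkness and 2.20 ± 0.05 after 2 months. Group 4, with 2891 IDs, stood at 1.44 ± 0.07 after 2 months, and at -0.90 ± 0.13 at 24 h after light return. Group 3, with 2971 IDs, stood at 0.89 ± 0.45 after 3 days of darkness, at -1.63 ± 0.10 after 2 months and at -2.50 ± 0.07 at 24 h after light return. Its value at 3 days turned to -0.12 with library totals alone. Group 6, with 2470 IDs, stayed at 0.05 ± 0.02 after 2 months of darkness and reached 3.20 ± 0.06 at 30 min after light return, or 1.78 with library totals alone. Its value at 2 months turned to -0.30 with RLE scaling factors. It was at 1.04 ± 0.18 by 6 h. Group 7, with 2350 IDs, moved to -1.54 ± 0.13 at the same 30 min. Group 5, with 2712 IDs, reached its highest value of 2.26 ± 0.08 at 6 h after light return.

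**Figure D2:**
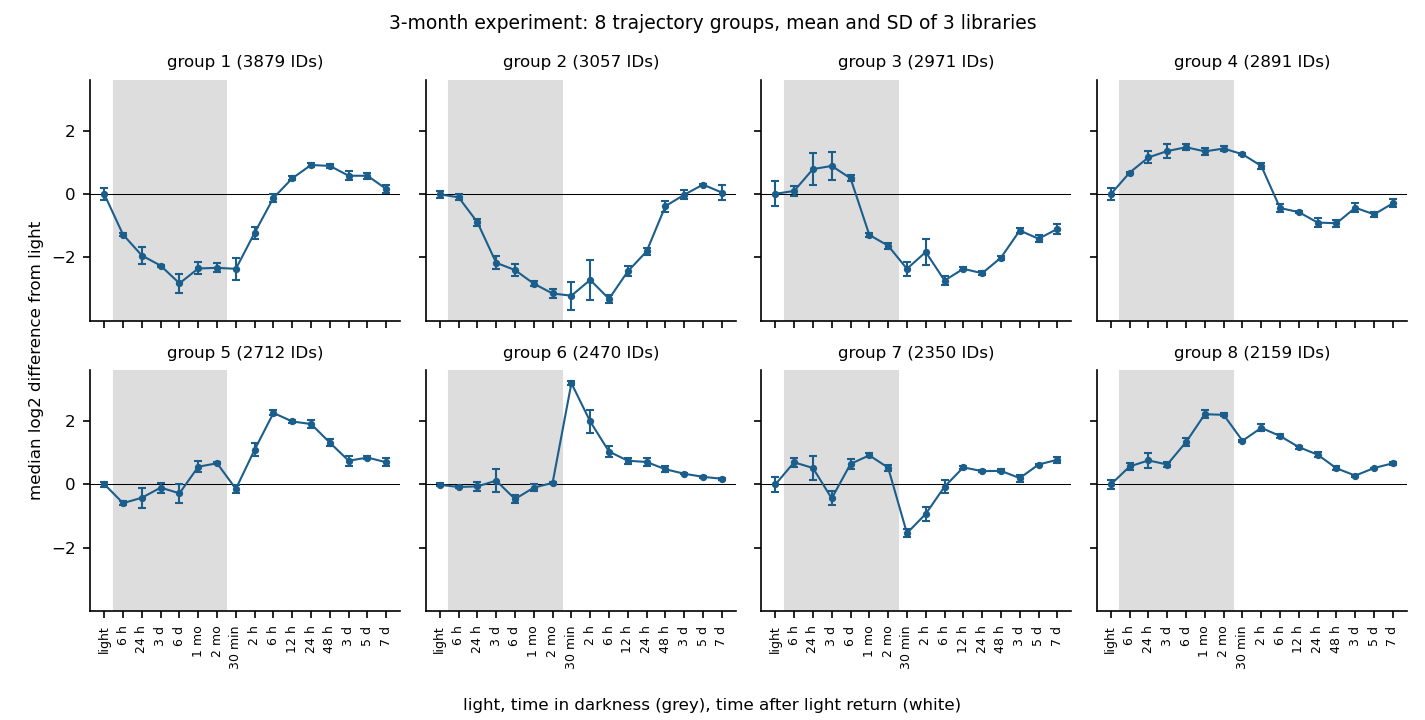
Median log2 difference from light (vertical axis) of the IDs in each of 8 trajectory groups over the 16 groups of the 3-month experiment, with darkness shaded grey. Points are means and bars SDs of 3 libraries. Group 6 peaks at 3.20 at 30 min after light return, group 5 at 2.26 at 6 h, and group 8 at 2.22 after 1 month of darkness.

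The immediate answer to light was read 30 min after light return. Against light, 6261 IDs were higher and 9784 lower, and against 2 months of darkness 5628 were higher and 7756 lower. A few transcripts took a large part of the counts at this time: the 7 most abundant IDs held 37.0% ± 9.36 (SD, n = 3) of a library, against 2.20% ± 1.59 in light, 9.75% ± 0.41 after 1 month of darkness and 5.61% ± 1.74 after 2 months. They held 12.7% ± 4.28 at 2 h after light return, 2.83% ± 0.98 at 6 h, 10.6% ± 7.77 at 12 h, 0.51% ± 0.15 on day 3, 7.57% ± 2.63 on day 5 and 7.68% ± 7.59 on day 7. These 7 IDs were chosen after their values were seen. The most abundant, ID 256583, held 12.3% ± 2.92, and ID 256585 held 11.7% ± 2.80. In light they held 0.46% ± 0.26 and 0.45% ± 0.25. Without the 7 IDs 13158 IDs were called against 2 months of darkness, of which 6007 were higher and 7151 lower. The split against light kept its direction under every scaling tried, and the split against 2 months of darkness turned. The median log2 difference of all tested IDs from light was -0.68, and library totals alone moved it to -2.10. Under that scaling 3178 IDs were higher than in light and 14475 lower, and 2699 were higher than after 2 months of darkness and 12922 lower. With RLE scaling factors 6856 were higher than after 2 months of darkness and 5703 lower, and DESeq2 gave 7338 and 5957.

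The following hours were compared with 30 min after light return. Against 30 min, 6143 IDs were higher and 4150.0 lower at 2 h, 7979 were higher and 6471 lower at 6 h, and 9330.0 were higher and 6509 lower at 24 h. ID 198172 had no count at 30 min and 323 ± 49.6 CPM (n = 3) at 24 h, at least 414-fold higher (adjusted p = 1.73e-14). ID 186233 had no count at 30 min and 112 ± 15.6 CPM at 24 h, at least 143-fold higher (adjusted p = 2.29e-14). ID 264519 went from 652 ± 139 CPM at 30 min down to 0.88 ± 0.49 at 24 h and fell by 9.48 ± 0.55 on the log2 scale (SE, adjusted p = 9.65e-18). ID 212519 went from 173 ± 0.13 CPM down to 0.26 ± 0.17 and fell by 9.35 ± 0.50 (adjusted p = 9.8e-19). Without replicate 3 of 24 h ID 264519 fell by 10.09. Scaling by library totals alone, 13452 IDs were higher and 1341 lower at 2 h, 13573 and 2411 at 6 h, and 15107 and 2607 at 24 h. RLE scaling factors gave 4379 and 5293 at 2 h, and DESeq2 4644 and 5571. At 2 h the split also turned in a fit of the 2 groups alone, to 3997 and 4022, and without replicate 3 of 2 h, to 4256 and 4811. At 6 h DESeq2 gave 7421 and 7534.

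Against light, 7389 IDs were higher and 7988 lower at 2 h after light return, and 7554 were higher and 8510.0 lower at 6 h. At 12 h 7625 were higher and 6939 lower, and at 24 h 7603 were higher and 6785 lower. At 2 h the split was 5876 and 9646 with RLE scaling factors and 6059 and 9914 with DESeq2. With library totals alone it was 9095 and 6777 at 6 h, 9983 and 5056 at 12 h, and 10171 and 4957 at 24 h. The excess of higher IDs turned at 12 h, with 6553 and 7693 for RLE scaling factors and 6960.0 and 7958 for DESeq2, and at 24 h, with 6948 and 7205 and with 7402 and 7454. Without the 7 dominant IDs it turned too, to 7178 and 7226 at 12 h and 6997 and 7109 at 24 h, and a fit of the 2 groups alone gave 7014 and 7023 at 24 h.

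The return to the light state was read from 48 h to 7 days after light return. At 48 h 6573 IDs were higher than in light and 5498 lower. On day 3 the numbers were 3050.0 and 3179, on day 5 they were 5556 and 4088, and on day 7 they were 5713 and 4331. Leaving out replicate 3 of day 3 gave 4101 called IDs in place of 6229. With library totals alone the split was 10073 and 3464 at 48 h, 6263 and 2011 on day 3, 6514 and 2930.0 on day 5, and 7074 and 2814 on day 7. Without the 7 dominant IDs the split turned to 5719 and 5939 at 48 h, 4324 and 4761 on day 5, and 4732 and 4859 on day 7. RLE scaling factors gave 4852 and 4888 on day 7. Fits of the 2 groups alone gave 6346 and 6348 at 48 h, 5377 and 5395 on day 5, and 4299 and 4441 on day 7. Against day 3 itself, in a comparison added after the data were seen, 4968 IDs were higher on day 7 and 4206 lower, which turned to 3667 and 4253 with library totals alone, and DESeq2 gave 5136 of each.

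The named IDs of day 7 against light took different courses before that day. ID 147959 had 3 counts in light and 1202 ± 325 CPM (n = 3) on day 7, a ratio of 10250.2 with a 95% counting interval of 3507 to 49706. ID 238205 had 2 counts in light and 91.4 ± 27.6 CPM on day 7, a ratio of 1206 with an interval of 334 to 9959. ID 257201 went from 1039 ± 781 CPM in light down to 0.74 ± 0.99 and fell by 10.36 ± 1.41 on the log2 scale (SE, adjusted p = 3.11e-07). ID 237462 went from 1419 ± 1046 CPM down to 1.08 ± 1.42 and fell by 10.27 ± 1.23 (adjusted p = 2.65e-08). IDs 147959 and 238205 were at 0.13 ± 0.14 and 0.08 ± 0.07 CPM in light, at 4.76 ± 2.23 and 0.52 ± 0.49 at 30 min after light return and at 3.49 ± 4.11 and 0.75 ± 0.77 at 2 h. They were at 0.23 ± 0.12 and 0.10 ± 0.03 on day 3, and at 555.4 ± 678 and 35.7 ± 43.2 on day 5. IDs 257201 and 237462 were at 135 ± 46.7 and 227 ± 123 CPM after 6 h of darkness, at 566 ± 759 and 761 ± 1104 after 24 h, at 0.66 ± 1.14 and 6.71 ± 8.41 after 1 month and at 0.04 ± 0.07 each after 2 months. Without replicate 1 of light, the ratio of ID 147959 was 22470.3 (4033 to 887545) and IDs 257201 and 237462 fell by 9.54 and 9.47 on the log2 scale, and without replicate 1 of day 7 they fell by 12.68 and fell by 12.39. Without replicate 2 of light the ratio was 6163 (2109 to 29884) for ID 147959 and 725 (201 to 5987) for ID 238205, and without replicate 2 of day 7 ID 257201 fell by 9.77. Against 2 months of darkness 9071 IDs were higher on day 7 and 6380.0 lower.

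The share of counts held by fixed sets of transcripts showed how the most abundant mRNAs turned over. The 100 IDs most abundant in replicate 1 of light held 18.3% ± 1.77 (SD) of the counts in the other 2 light libraries. They held 23.4% ± 3.03 (n = 3) after 6 days of darkness, 11.6% ± 0.63 after 1 month and 7.87% ± 1.99 after 2 months. A light set chosen without the 7 dominant IDs, after the data were seen, held 21.0% ± 1.32, 3.86% ± 0.69 and 3.39% ± 0.27 at these times. The 100 IDs most abundant in replicate 1 of 2 months of darkness held 10.6% ± 0.51 after 6 h and 27.9% ± 1.10 after 1 month of darkness, and 4.59% ± 1.53 at 24 h after light return. Chosen without the dominant IDs, it held 9.97% ± 0.495, 20.9% ± 1.38 and 2.92% ± 0.27 at these times. The light set included 3 of the 7 dominant IDs and the dark set all 7. At 30 min after light return the light set held 31.7% ± 6.45, and the light set chosen without the dominant IDs held 3.26% ± 0.01.

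**Figure D3:**
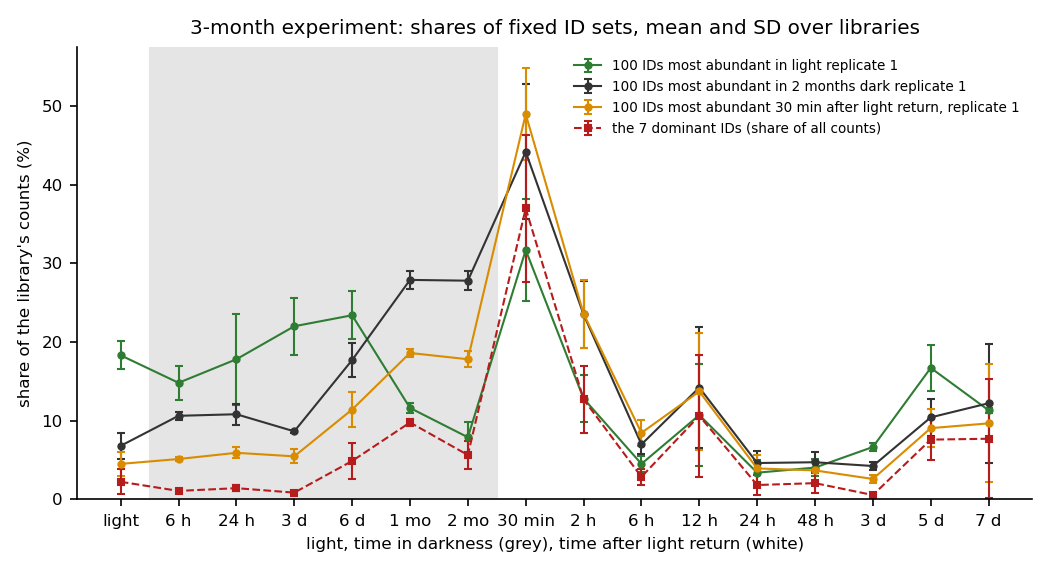
Share of a library's counts (percent) held by 3 sets of 100 IDs, each the most abundant in replicate 1 of the named group, and by the 7 dominant IDs, over the 16 groups of the 3-month experiment. Points are means and bars SDs over 3 libraries, or 2 where the set was chosen in the group's replicate 1. The light set holds 18.3% in light and 7.87% after 2 months of darkness, and the 7 dominant IDs hold 37.0% at 30 min after light return.

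The 1-month experiment came as a separate table that did not rank IDs as the 3-month table did. Across IDs, which are not independent replicates, the Spearman correlation of mean CPM in light between the tables was 0.47, and over the 6 conditions of the 1-month experiment it ran from 0.44 at 30 min to 0.55 at 6 h after light return. Between different conditions of the 3-month table it was 0.49 or higher. The 100 most abundant IDs of 1-month light lay at a median percentile of 22.5 in 3-month light, whereas the 100 most abundant IDs of 3-month light lay at 98.04 in 1-month light. IDs below the median of the 3-month table held 65.2% of the 1-month light counts. Which strand was counted is not given in the sources used here, and this limit holds for every value of the 1-month experiment below.

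**Figure D4:**
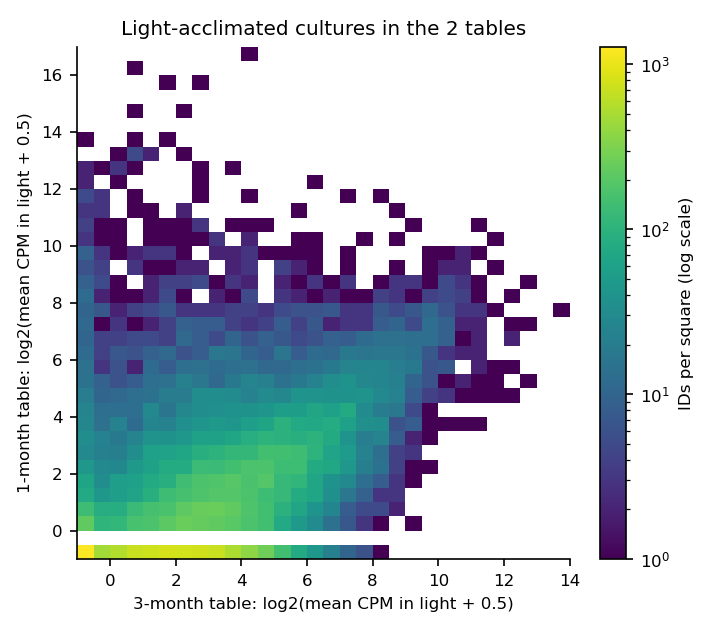
Number of IDs by log2 of mean CPM plus 0.5 in light in the 3-month table (horizontal) and in the 1-month table (vertical), in squares of 0.5 by 0.5 log2 units, with a logarithmic colour scale. IDs at the upper left are abundant in the 1-month table and near 0 in the 3-month table, and the Spearman correlation is 0.47.

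One month of darkness was compared with light in this experiment too. Of 5056 IDs tested, 709 were higher and 853 lower. Replicate 2 of 1 month stood apart, with 9736 IDs detected against 14147 and 21075 in replicates 1 and 3. Its 10 most abundant IDs held 66.0% of the counts, against 39.5% and 43.4%. Without this library 848 IDs were higher and 956 lower. A set of 9 IDs that dominated some libraries of this table held 42.6% ± 17.4 of the counts after 1 month and 8.69% ± 2.11 in light. In light the 10 most abundant IDs held 40.6% ± 4.36. The set was not high in darkness alone. It held 54.5%, 15% and 11.4% in replicates 1, 2 and 3 of 30 min after light return, and 5.7%, 7.72% and 42.9% on day 7. ID 232215 had no count in light and 199.5 ± 138 CPM (SD, n = 3) after 1 month, at least 25.2-fold higher (adjusted p = 0.000604). ID 268266 had no count in light and 135 ± 117 CPM after 1 month, at least 17.1-fold higher (adjusted p = 2.14e-05). ID 237322 went from 890.3 ± 706 CPM down to 1.68 ± 1.55 and fell by 8.96 ± 1.56 on the log2 scale (SE, adjusted p = 0.000604). ID 224737 went from 2316 ± 1734 CPM down to 4.99 ± 6.19 and fell by 8.44 ± 1.05 (adjusted p = 6.39e-06). Without replicate 1 of 1 month the bound of ID 268266 was 9.27-fold, and without replicate 3 of light ID 224737 fell by 7.68. Without replicate 3 of 1 month the ratios of light to darkness were 889 (159 to 35153) for ID 237322 and 1111 (307 to 9179) for ID 224737. The 2 groups fitted by themselves gave 907 called IDs, and library totals alone 375 higher and 912 lower. No low-count filter turned the split to 795 higher and 650.0 lower.

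Few transcripts were called at 30 min after light return in the 1-month experiment. Against 1 month of darkness 17 IDs were higher and 6 lower, with 672 at an unadjusted p under 0.05. ID 237644 rose by 4.90 ± 0.95 on the log2 scale (SE, n = 3, adjusted p = 0.012 in edgeR) and ID 194585 by 4.69 ± 0.93 (adjusted p = 0.0136). ID 255290 fell by 4.60 ± 0.97 (adjusted p = 0.0174) and ID 254817 fell by 3.84 ± 0.85 (adjusted p = 0.0294). The 2 groups fitted by themselves gave 0 called IDs, with 294 at an unadjusted p under 0.05, and edgeR's adjusted p of 0.21 to 0.302 for these 4 IDs. Over all edgeR alternatives their adjusted p ran from 0.000343 to 0.313. DESeq2 called 124, of which 70 were higher and 54 lower, edgeR without a low-count filter 43, of which 18 were higher and 25 lower, and library totals alone 28 higher and 0 lower. Leaving out replicate 2 of 1 month of darkness gave 58, with IDs 255290 and 254817 falling by 2.51 and 1.60 (adjusted p = 0.224 and 0.313 in edgeR), and leaving out replicates 1, 2 and 3 of 30 min gave 13, 8 and 7. Without replicate 3 of 1 month of darkness, which left 1 count there, the split was 15 and 15 and the ratios were 78.6 (13.7 to 3142) for ID 237644 and 76.8 (13.4 to 3069.8) for ID 194585. At this depth and spread between replicates, simulated 4-fold changes were recovered in 7% of IDs and 2-fold changes in 0%. These shares hold for 200 changed IDs among 5056, since the adjusted p is stricter where few IDs change.

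Later times of the 1-month experiment differed from darkness in more IDs. At 6 h after light return 492 IDs were higher and 392 lower than after 1 month of darkness, at 24 h 1076 were higher and 904 lower, and on day 7 there were 1021 higher and 721 lower. Against light, 590.0 IDs were higher and 796 lower at 30 min, 902 and 898 at 6 h, 735 and 814 at 24 h, and 251 and 157 on day 7. With library totals alone the splits against darkness were 1228 and 52 at 6 h and 1817 and 246 at 24 h, and against light 1219 and 421 at 6 h, 1132 and 348 at 24 h, and 56 and 145 on day 7. RLE scaling factors gave 634 and 307 at 6 h and 1383 and 683 at 24 h against darkness, and 1024 and 682 at 24 h against light. No low-count filter turned the splits against darkness to 266 and 340.0 at 6 h and 799 and 1009 at 24 h. DESeq2 gave 1505 and 772 at 24 h against darkness, and 1135 and 743 at 24 h against light. At 6 h against darkness, leaving out replicate 1 of 1 month of darkness turned the split to 263 higher and 295 lower, and leaving out replicate 3 of 6 h gave 465 called IDs. At 6 h against light the split turned to 869 and 897 with the replicate block, and to 900.0 and 902 without the 7 dominant IDs. It was 706 and 779, 644 and 771, and 823 and 843 without light replicates 1, 2 and 3, and 731 and 751 without replicate 1 of 6 h. At 24 h against light a fit of the 2 groups alone gave 827 and 802. Against light, leaving out replicate 2 of light gave 980.0 at 24 h. On day 7 the number was 246, 264 and 252 without light replicates 1, 2 and 3, and 239 without replicate 3 of day 7.

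Whether the change from light differed between the experiments was tested as an interaction in a joint fit of 23611 IDs. That fit gave both experiments 1 spread per ID, although the spread was wider in the 1-month experiment when each was fitted by itself. For 1 month of darkness 5857 IDs differed, of which 1733 changed more positively in the 3-month experiment and 4124 more negatively. Over all tested IDs the median interaction was -1.79 on the log2 scale, or -0.62 with DESeq2. In the separate fits the median changes were -0.21 in the 3-month and 0.06 in the 1-month experiment. Fitted by itself, the 1-month experiment had 5056 IDs past the low-count filter. The joint fit called 3359 IDs in the 1-month experiment, where its own fit called 1562. In the joint fit 2294 IDs were called in both experiments, and 1686 of them (73.5%) changed in the same direction. Independent lists would share 1056.9 IDs in the same direction. In the separate fits, over the 4851 IDs tested in both, 1127 were called in both and 775 (68.8%) changed in the same direction. Independent lists would share 557.2 there. For day 7 after light return 2579 IDs differed, 773 more positively in the 3-month experiment and 1806 more negatively. Here the joint fit called 1192 IDs in the 1-month experiment, where its own fit called 408. Of 469 IDs called in both by the joint fit, 213 (45.4%) changed in the same direction, where independent lists would share 203.1. In the separate fits 204 were called in both and 93 (45.6%) changed in the same direction, where independent lists would share 96.3. The split for day 7 was 1373 and 1177 with RLE scaling factors, 1702 and 756 with library totals alone, and 1919 and 1216 with DESeq2. Experiment and table are the same division of the libraries, so these differences hold those of the tables.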

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

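In this part, the tests of shifted rows and of a difference between the experiments were chosen only after the result was seen.

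The response to 1 month of darkness was called different between the experiments in 5857 IDs by edgeR's test of the interaction. The state on day 7 after light return was called different in 2579 IDs. The joint fit gave both experiments 1 spread per ID. Fitted separately, the common biological coefficient of variation was 0.32 in the 3-month and 0.52 in the 1-month experiment. The joint fit tested 23611 IDs, where 5056 passed the low-count filter in the 1-month experiment by itself. How far this raised the counts was not tested. In fits of the 4 groups alone the counts were 4963 and 2334. Among 100 splits of the 12 libraries drawn for each, the real one included, none of the other splits gave as many, with 4533 and 1007 IDs in the highest of them. In both cases that split kept the 3-month groups apart and mixed the 1-month groups, and splits that kept neither apart gave at most 0. Splits that mix conditions widen the spread within groups and lose that experiment's response, so their low counts were to be expected. Splits that keep the 3-month groups apart are too few for a share under 0.05. A random division is thus not excluded as the source of the interactions. For 1 month of darkness, most of such a count can arise from the response of the 3-month experiment alone.

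The 2 tables ranked IDs differently in the same condition, which bears on both interactions. Lower depth is argued against, since 3-month light libraries thinned to the 1-month totals kept a Spearman correlation of at least 0.89 with other 3-month light libraries, against at most 0.415 between single light libraries of the 2 tables. Shifted rows are argued against too, since the best offset other than 0 gave 0.181 against 0.467 at 0 for the mean light values. The tables may have been counted on opposite strands, but this cannot be told apart from other causes. The shares compared were those of the 9 IDs that dominated some 1-month libraries and of the 7 dominant IDs of the 3-month table. The SD of their log2 ratio was 0.925 over the 48 libraries of the 3-month table. It lay between the bounds set beforehand by the SD of the share of the 7 IDs, 1.74. Over the 18 libraries of the 1-month table the ratio was steadier, with an SD of 0.215 against 1.02 and the smaller share at 0.505% to 0.803% of the larger, which goes with opposite strands but was not the value the bounds were set for. A biological difference between the experiments also stays open, because experiment and table divide the libraries alike. Between conditions of the 3-month table the lowest correlation of group means was 0.489 and the median 0.694. The same condition correlated less than 0.489 between tables in light, 0.467, and after 1 month of darkness, 0.483. After light return this also held at 30 min, 0.436, at 24 h, 0.46, and on day 7, 0.47. Only 6 h after light return lay above it, at 0.552. The tables thus differed more in most conditions than unlike conditions did within the 3-month table.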

How the results depend on the processing

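Leaving out the 7 dominant IDs and the comparisons of 2 months with 1 month of darkness and of day 7 with day 3 were chosen only after the data were seen. Of 33 counts of called IDs, 33 stayed within 1.5 times of the reported value with RLE scaling factors and without the 7 dominant IDs, and 32 each with DESeq2, library totals alone and no low-count filter. With only the 2 groups compared in the fit 27 of 31 did, with only the 4 groups of an interaction 2 of 2, and with 1 library left out 195 of 210. The 7 dominant IDs held a mean of 0.0561% to 0.25% of the counts in the 1-month groups. Leaving them out was thus no test of the 1-month counts. The set of 9 IDs that held up to 62.6% of a 1-month library was not left out. With only the 2 groups compared, the 1-month experiment gave 907 IDs in place of 1562 for darkness against light, 0 (294 at an unadjusted p under 0.05) in place of 23 for 30 min after light return against darkness, and 1085 in place of 1742 for day 7 against darkness, and the 3-month experiment gave 4242 in place of 2311 for 2 months against 1 month of darkness. For 30 min against darkness in the 1-month experiment DESeq2 gave 124 and no low-count filter 43, and for its day 7 against light library totals alone gave 201 in place of 408. The cause was not tested. With 1 library left out, the 1-month experiment gave 980.0 to 1380.0 IDs for 24 h against light, 7 to 58 for 30 min against darkness, 465 to 971 for 6 h against darkness and 239 to 432 for day 7 against light, and the 3-month experiment gave 1225 to 2101 for 2 months against 1 month of darkness and 4101 to 5732 for day 3 against light, each with fewer libraries in the fit. Of the values of the 24 named IDs under alternatives, 294 kept their direction and side of the threshold and 15 kept the direction alone, all of the 4 IDs named for 30 min in the 1-month experiment. DESeq2 gave no adjusted p for 1 further value. The gene list tests and their alternatives were not run. In the 1-month experiment, with totals from 287268 counts and a common biological coefficient of variation of 0.52, 7% of simulated 4-fold changes were recovered where 200 IDs changed.

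With the replicate number as a block, all 33 counts stayed within 1.5 times, with 9605 IDs for 6 h of darkness in the 3-month experiment and 26 for 30 min against darkness in the 1-month experiment. The labels share only a number: deviations of same-numbered libraries correlated by 0.04 on average in the 3-month experiment, with 105 of 360 pairs over 0.1, and by 0.02 in the 1-month experiment, with 4 of 45. As a hint from the data, 33 of 48 and 9 of 18 libraries correlated best with their own number, with 3 numbers to choose from. The main fits treat all libraries as independent, whether or not a number marks 1 culture followed over time.

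The comparisons of 3 with 3 libraries allow 10 splits, too few for a share under 0.05. In fits of the 2 groups alone the real splits gave 4242 to 15225 IDs in 22 comparisons of the 3-month experiment and 373 to 1696 in 8 of the 1-month experiment, and the highest of the other splits gave 0. Each of those other splits puts libraries of both conditions in each group, which widens the spread within groups. Their 0 calls were thus to be expected and are no measure of chance. For 30 min against darkness in the 1-month experiment all 10 splits gave 0 by edgeR.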

Other observations

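In this part, the tests of the third month of darkness and of the regained share were chosen only after the result was seen, as was the repeat without the 7 dominant IDs.

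The hypothesis that the transcripts most abundant in light lose their share of the counts in darkness was tested with the 100 IDs most abundant in replicate 1 of light. They held at most 9.64% in a library of 2 months of darkness, against at least 17.0% in the other 2 light libraries, as the hypothesis predicts for long darkness. Choosing the set in light favours a lower share in other groups without fixing it, so this fall is weak evidence. The set chosen in replicate 1 of 2 months of darkness likewise held 27.8% in the other 2 libraries of that group and 6.78% in light. The share of the light set did not fall during the first week as a whole. It was 14.8% ± 2.19 (SD, n = 3) after 6 h of darkness, 22.0% ± 3.64 after 3 days and 23.4% ± 3.03 after 6 days. At 6 days it ran from 21.2% to 26.9%, above the highest light library at 19.5%. A set without the dominant IDs, chosen after that value was seen, held 3.39% ± 0.27 after 2 months. The further hypothesis that the share stands regained on day 7 after light return did not hold, since the highest share on day 7 was 11.7%. The choice of the set in light limits this result too. On day 5 the share was 16.7% ± 2.94, from 14.9% to 20.1%, which overlapped the light libraries, and 12.0% ± 1.47 for the set without the dominant IDs.

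Many more IDs differed between 30 min after light return and the last dark sample in the 3-month experiment than in the 1-month experiment. The numbers were 13384 of 22642 IDs tested and 23 of 5056. Without the 7 dominant IDs 13158 IDs were called, so these IDs are not needed for the difference. Whether the share of counts they took played a part is not decided, since TMM scaling already allows for a few abundant IDs. Lower depth is argued against as the whole cause, since 10 thinnings of the 3-month libraries to the 1-month totals gave at least 5448 called IDs, against 0 in the matching fit of the 1-month experiment. Thinning keeps the spread between the 3-month replicates. The common biological coefficient of variation was 0.52 in the 1-month and 0.32 in the 3-month experiment, and its part in the difference was not tested. The third month of darkness may have added to the difference, and cannot be told apart because its libraries were not analysed here, while the second month changed 2311 IDs. The difference of the tables and the length of darkness, a biological explanation, stay open.

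Fewer IDs differed from light on day 3 after light return, 6229, than on day 5, 9644, or day 7, 10044. Depth is argued against, since after thinning to 1 total day 3 gave 6812 IDs and the lower of the other days 10695. The same fit, of light and days 3, 5 and 7 alone, gave 7118 and 10931 without thinning. A single library out of place is argued against, since leaving out any 1 library gave at most 5732 IDs on day 3 and at least 7181 on days 5 and 7. The scaling may account for part of the gap, since with library totals alone day 3 gave 8274 IDs against 9444, above 0.8 times that value, the bound set beforehand. A biological change between day 3 and day 5 stays open and untested.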
